A study of Mus musculus with 4 samples.

How the data were processed

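Total RNA from mouse left ventricle was hybridised to 4 Affymetrix-type arrays with biotin label, 1 per group: wild-type sham, wild-type banded, IL-18 null sham and IL-18 null banded. Groups were taken from the sample titles, and per the labels the IL-18 null mice were on a C57BL/6 background. The deposited values are intensity values on a linear scale with 1 decimal per probe set, and the authors computed them with GCRMA per the submitters' processing notes. The version and settings of GCRMA, the scanner settings and any later scaling were not given in the sources used here. That the scale is linear was read from the range of the values, from 1.5 to 43811.1. No scanner files were analysed here, and the number of arrays limits the precision.

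The table held 22690 probe sets. Of these 64 were control probe sets, 20380 had 1 gene in the platform annotation used here, 691 had several and 1555 had none. Probe sets with several genes or none and control probe sets were left out of the comparisons. Symbols were checked through the gene identifier against the mouse RefSeq table of assembly GRCm38.p6: 20351 matched and 0 symbols changed. Each of 12393 genes was represented by the probe set with the highest mean over the 4 arrays; 4956 genes had several. Intensities below 1 would have been set to 1 before taking log2. Values below a floor of log2 6 (64 intensity units) were then set to the floor before differences were taken, so a gene below the floor on 1 array gives a bound. A gene entered a comparison when at least 1 of its arrays was at or above the floor. This left 5158 genes measured on at least 1 array and 7235 below the floor on all.

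The choices of floor, probe set, fold threshold, gene lists, named genes and alternatives were made before the data were examined, except the 3′ bias index and its use as a covariate. The 4 main comparisons set 2 arrays against each other: banding in each genotype, and genotype in each surgery. Another took the difference of the banding responses between genotypes. Genes were counted at a log2 difference of at least 1 (2-fold), with no test. Shared genes were counted beside the number that independent lists would share, and differences were correlated across genes. The secondary test was limma's moderated test (lmFit and eBayes with an intensity trend) on unfloored log2 values, with surgery and genotype as terms, 1 residual degree of freedom and Benjamini-Hochberg adjustment. The 2-fold counts were tested on simulated data of 4756 genes for wild-type banding, of which 200 were changed, with a noise SD of 0.272 per array taken from the IL-18 null pair. They recovered 94% of genes changed by 1.5 (log2) and 100% of those changed by 3, and for IL-18 null banding, over 4766 genes, 90% and 100%; of unchanged genes 0.658% and 0.876% passed. With the larger spread of the wild-type pair taken as noise (SD 0.685, 4934 genes), the recovery in wild-type banding was 72% and 97%, and 26.2% of unchanged genes passed. At the smaller noise the additive fit recovered 100% of both sizes among 4867 genes. With noise of the size of its residual on these arrays (SD 0.565, 5092 genes) it recovered 28% and 97%, in simulated data with the same noise for every gene.

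Genes were named by a rule: the 10 largest differences in each direction among genes at or above the floor on both arrays (on all 4 for the difference of responses), and up to 10 shared genes per direction by the smaller size. From each list up to 4 members with the largest differences were taken, with any member of the hypertrophy and IL-18 pathway lists, and always Il18, Nppa, Nppb, Myh7, Acta1, Myh6 and Atp2a2. Gene lists numbered 32: hypertrophy, adult contractile and calcium-handling, extracellular matrix, fatty acid oxidation, oxidative phosphorylation, citric acid cycle, glucose and glycogen, IL-18 pathway, interferon response, antigen presentation, macrophage, T and NK cell, B cell, neutrophil, mast cell, endothelial, smooth muscle and pericyte, fibroblast, red cell, atrial, adipocyte, skeletal muscle, immediate-early, circadian, cell cycle, heat shock and endoplasmic reticulum stress, antioxidant and metal, glucocorticoid response, Wnt signalling, ribosomal protein, sex chromosome and strain marker genes. A list's median was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression. The region within 10 Mb of Il18 was compared with the rest of the genome by Fisher's exact test, two-sided.

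Alternatives were floors at log2 5 and 7 and no floor, quantile normalization, cyclic loess, the mean of all probe sets of a gene, leaving out probe sets marked as shared between transcripts, a 1.5-fold threshold, an adjusted p of 0.1, limma without the trend, random lists not matched on expression, and a window of 20 Mb. After the control probe sets were seen, the additive fit with the 3′ bias index as a covariate was added; it has as many terms as arrays, so its banding and genotype terms are fixed mixtures of 2 differences each and it tests nothing about the bias. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.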

Results

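Gene expression in the left ventricle was measured on 4 arrays, 1 for each combination of genotype (wild type or IL-18 null) and surgery (sham operation or transaortic banding, which narrows the aorta and overloads the ventricle with pressure). The question named by the series is the role of the cytokine IL-18 in gene expression during hypertrophy caused by pressure overload. Each array carried RNA pooled from several mice: 5 for the sham IL-18 null pool and 6 for the banded IL-18 null pool per the labels, and 5 to 6 per group per the series design. A banding time of 1 week is labelled for the IL-18 null banded pool. The banding time and pool size of the wild-type pools were not given in the sources used here beyond the series design, so whether both genotypes were banded for the same time could not be checked. With 1 pooled array per group, no difference below has a replicate check or an error, and no p-value is given for any comparison of 2 arrays. All differences are on the log2 scale. "At least" or "a bound" marks a difference in which 1 array lay below the floor of 64 intensity units. Percentiles place the median of a gene list among 10000 random lists of the same size and expression, and describe these arrays only.

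The arrays gave 5158 genes at or above the floor on at least 1 array, out of 12393 with a probe set of their own. Median intensity over all 22690 probe sets was 13.7 in wild-type sham, 11.3 in wild-type banded, 11.6 in IL-18 null sham and 11.6 in IL-18 null banded. The share of probe sets at or above the floor was 29.2%, 32.3%, 31.0% and 31.3% in the same order. Il18, the deleted gene, had a log2 intensity of 3.19 in wild-type sham, 2.89 in wild-type banded, 3.04 in IL-18 null sham and 3.07 in IL-18 null banded. All 4 values lay below the floor, so Il18 could not check the genotype labels, and every comparison rests on the labels as given.

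The arrays differed in how strongly signal was concentrated at the 3′ ends of transcripts. Gapdh, a glycolytic enzyme that the array probes at 3 positions, had log2 intensities of 10.998 at the 3′ end and 6.39 in the middle in wild-type sham, against 13.90 and 14.06 in wild-type banded. The IL-18 null arrays lay between them, at 13.39 and 10.66 for sham and at 13.58 and 11.92 for banded. A 3′ bias index, the mean over Gapdh, Actb and the bacterial control dap of the 3′ minus the middle probe set, was 4.74 ± 0.14 in wild-type sham and 0.72 ± 1.14 in wild-type banded (SD over 3 transcripts). It was 3.37 ± 1.14 in IL-18 null sham and 3.01 ± 1.47 in IL-18 null banded. These values are unfloored. In wild-type sham the middle probe sets of Actb and dap lay below the floor, and with values set to the floor the index there was 3.04 ± 1.53, a bound. The mean 3′ minus 5′ value of the same transcripts, also unfloored, was 4.81 ± 1.08, 1.33 ± 0.97, 4.81 ± 1.64 and 4.84 ± 2.20 in wild-type sham, wild-type banded, IL-18 null sham and IL-18 null banded. Another bacterial control, thr, whose middle probe set lay below the floor on every array, had 3′ minus middle values of 2.84, 2.86, 4.55 and 5.78 in the same order and was left out of the index. The hybridisation controls cre and bioD, added after labelling, had 3′ minus 5′ values between -0.27 and 0.50. Wild-type banded thus had the lowest value by each of these 3 means, though not for thr, and these controls did not settle the order of the other arrays.

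**Figure D1:**
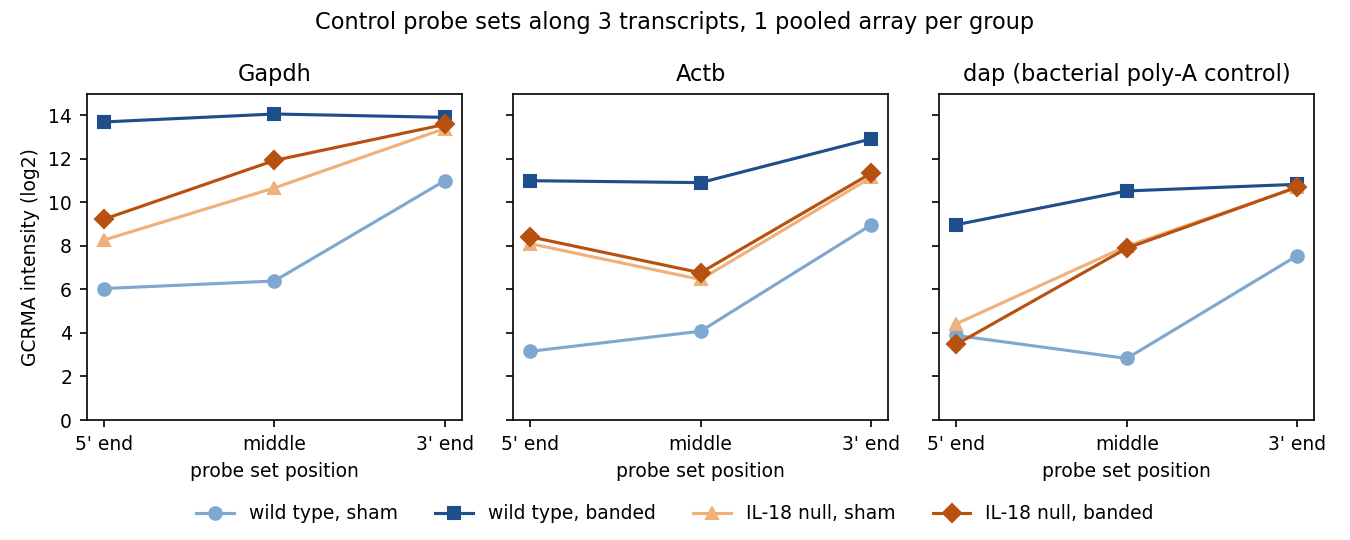
GCRMA log2 intensity of the 5′, middle and 3′ probe sets of Gapdh, Actb and the bacterial control dap, 1 line per pooled array. The wild-type banded line is nearly flat for Gapdh (13.69 at the 5′ end, 13.90 at the 3′ end), and the wild-type sham line is the lowest at the middle and 3′ positions of all 3 transcripts.

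Across the 5158 genes the arrays correlated with Pearson's r from 0.774, between the wild-type arrays, to 0.952, between wild-type banded and IL-18 null sham. Wild-type sham stood apart from every other array, with r of 0.871 to IL-18 null sham and 0.863 to IL-18 null banded. Wild-type banded correlated at 0.927 with IL-18 null banded. The IL-18 null arrays correlated at 0.951 with each other. These correlations run across genes, which are not independent replicates.

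In both genotypes, the banded array had higher signal for genes of the fetal and stress programme that marks cardiac hypertrophy. Nppa, which encodes atrial natriuretic peptide, was higher by 1.41 in wild type and by 2.5 in IL-18 null. Nppb, which encodes the B-type peptide, was higher by 1.38 and 1.14, and Myh7, the slow myosin heavy chain, by 1.90 and 3.32. Acta1, skeletal alpha-actin, was higher by 6.24 and 1.82, and Rcan1, a target and modulator of calcineurin, by 2.28 and 2.48. Of the 20 measured members of the hypertrophy list, 10 were at least 2-fold higher and 0 lower in wild type, with a median of 1.18 (percentile 99.98). In IL-18 null, 9 were higher and 0 lower, with a median of 0.67 (percentile 100). Nppa, Nppb, Myh7, Acta1 and Rcan1 were the 5 members at least 2-fold higher in both genotypes. Without banding, 6 of the 20 were at least 2-fold higher and 0 lower in IL-18 null than in wild type (median 0.22, percentile 94.6). Acta1 and Rcan1 were among these 6, so their wild-type differences cannot be credited to banding alone. Myh6, the adult myosin heavy chain, differed by 0.15 in wild type and 0.14 in IL-18 null, but its probe set was the brightest on the wild-type sham array (log2 15.13) and left little room for a difference. Its other measured probe set was at least 2-fold higher in wild-type banding. The calcium pump gene Atp2a2 differed by 0.54 and -0.20, while of its 3 other probe sets 2 were at least 2-fold higher in wild type and 1 at least 2-fold lower in IL-18 null.

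Extracellular matrix genes were higher in both banded arrays too. In wild type 23 of 45 measured members were at least 2-fold higher and 2 lower (median 1.00, percentile 100); in IL-18 null 27 were higher and 1 lower (median 1.37, percentile 100). The members higher in both genotypes numbered 16, among them Col1a1 (2.43 and 2.85), Mmp2 (at least 2.5, and 1.92), Col6a2 (1.80 and 2.79) and Mfap5 (2.84 and 2.29). Col8a1, a short-chain collagen, was higher by at least 2.26 and at least 3.06. Without banding, 11 of the 45 were at least 2-fold higher and 2 lower in IL-18 null than in wild type (median 0.00, percentile 77.2). Col1a1 was among these 11, so its wild-type difference cannot be credited to banding alone. The fibroblast marker list, which shares Col1a1, Col1a2, Col3a1, Mfap5, Dcn and Lum with the matrix list, had 8 of 15 members higher and 1 lower in each genotype, with medians of 1.03 and 1.06. The lower member in both was Scara5 (-1.24 and -1.51).

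In total 92 genes differed at least 2-fold the same way with banding in both genotypes, 79 higher and 13 lower, where independent lists of the same lengths would share 71.6 and 15.3. Among the others shared, Uck2, a uridine kinase, was higher by at least 2.15 and by 2.97, and Hsd17b12 by 2.01 and 1.72. The lower ones included the histone deacetylase gene Hdac11 (-3.15, a bound, and -1.74), the immediate-early gene Fos (-7.19, a bound, and -1.45), Ppargc1a, a coactivator of mitochondrial genes (-1.18 and -1.42), and Rgs2 (-2.00 and -1.16). Vsir, Tceal1, Prxl2a, Fech and Zdhhc14 completed the 10 named as lower in both; with the mean of all probe sets of a gene, Ppargc1a and Fech were at 0.40 and 0.38 in wild type. Another 63 genes were higher in wild type and lower in IL-18 null, against 25.9 for independent lists, and 44 went the other way, against 42.3. Across genes the banding differences of the 2 genotypes had Pearson's r of -0.084 and Spearman's rho of -0.083.

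**Figure D2:**
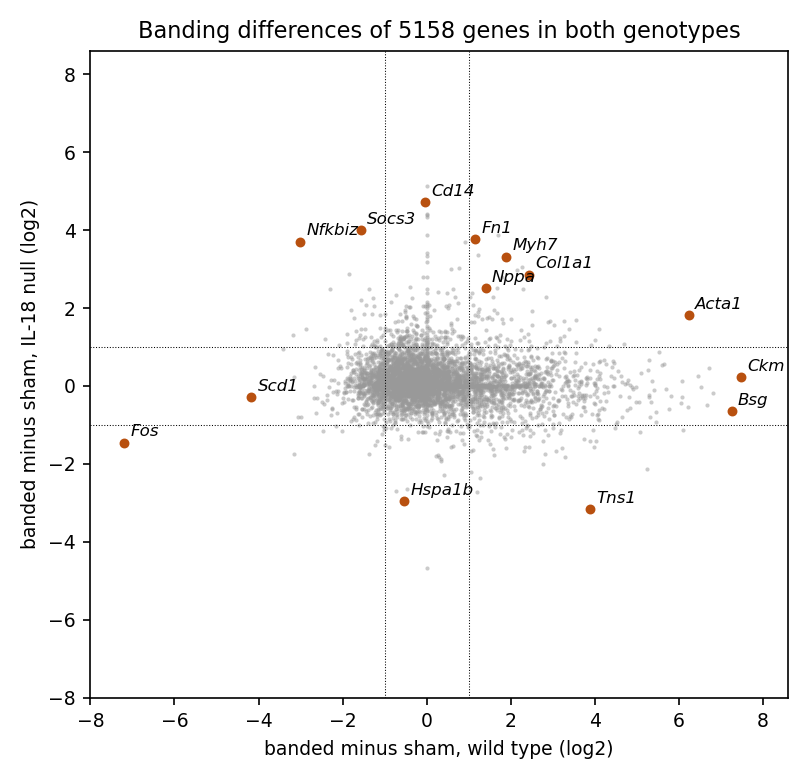
Banded minus sham log2 difference in wild type (x axis) against that in IL-18 null (y axis) for 5158 genes, 1 grey point per gene, with dotted lines at 2-fold and selected genes in orange. Myh7, Col1a1 and Nppa lie high on both axes; Ckm and Bsg lie high in wild type alone, and Cd14 in IL-18 null alone (4.71 against -0.03).

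Between the wild-type arrays, genes of muscle energy use and contraction were among the largest differences, higher in banded. Ckm, muscle creatine kinase, was higher by 7.49, Pfkm, muscle phosphofructokinase, by 6.05, Hadha, a beta-oxidation enzyme, by 5.28, and Ogdh, an enzyme of the citric acid cycle, by 5.07. These genes were also higher in the unbanded IL-18 null sham array than in wild-type sham, as given below. Both comparisons subtract the same wild-type sham array, so low signal on that array alone could give both results. Glucose and glycogen genes had 13 of 22 measured members higher and 1 lower (median 1.27, percentile 100), with Pygm higher by at least 6.08, Pygb by 4.43 and Pkm by 4.05. Adult contractile and calcium-handling genes had 7 of 22 higher and 1 lower (median 0.59, percentile 99.7), and endothelial markers 8 of 19 higher and 0 lower (median 0.90, percentile 99.9), with Emcn at 3.24 and Sox18 at 3.02. Oxidative phosphorylation genes had 15 of 62 higher and 0 lower (median 0.16, percentile 98.5). After quantile normalization their median was -0.03, while that of all genes moved from -0.08 to -0.42. The lists that hold Hadha and Ogdh did not stand apart. Fatty acid oxidation genes had 8 of 26 higher and 1 lower (median 0.00, percentile 58.5; -0.16 after quantile normalization). Citric acid cycle genes had 5 of 17 higher and 0 lower (median 0.08, percentile 73.5; -0.13 after quantile normalization). All groups in wild type, hypertrophy and matrix genes included, were compared between arrays with a 3′ bias index of 4.74 (sham; 3.04 as a bound with the floor) and 0.72 (banded).

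Other large differences in wild type were Bsg (7.26), the autophagy gene Map1lc3a (6.82), Eif5a (6.54), the ATP synthase gene Atp5g2 (6.09) and Tle5 (5.60). Among genes at or above the floor on both arrays, Scd1, a fatty acid desaturase, was the lowest (-4.17). After it came the immediate-early gene Egr2 (-3.15), the mitotic gene Cenpf (-3.06), Nfkbiz, a regulator of NF-kappa-B targets (-3.02), and Cited2 (-2.99). Cntd1 (-2.88), Sirt1 (-2.67), Btg2 (-2.65), Tmtc4 (-2.62) and Zfp281 (-2.54) followed. Bounds, such as that of Fos, were left out of this ranking. Of immediate-early genes, 7 of 18 were lower and 0 higher (median -0.27, percentile 21.6). The IL-18 pathway and macrophage lists did not stand apart in wild type: the IL-18 pathway list had a median of 0.00 (4 of 16 higher, percentile 58.6) and the macrophage list -0.20 (5 of 16 higher and 2 lower, percentile 24.6). The neutrophil list, with 4 measured members, had a median of -1.29 (0 higher and 2 lower, percentile 0.21), with S100a9 at -3.41 and S100a8 at -1.67, both bounds.

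In all, 1743 of 5040 genes differed at least 2-fold between the wild-type arrays, 1096 higher and 647 lower in banded; the split was 852 higher and 1272 lower after quantile normalization and 1238 and 426 after cyclic loess. For 407 of the higher and 80 of the lower genes the difference was a bound, since 1 array lay below the floor. Of the 20 genes with the largest differences among those at or above the floor on both arrays, 3 had other measured probe sets. Those of Btg2 disagreed, 1 of them being at least 2-fold higher.

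In IL-18 null, where the 3′ bias index was 3.37 in sham and 3.01 in banded, the banded array stood out by inflammatory and matrix genes. Cd14, the co-receptor for bacterial lipopolysaccharide on myeloid cells, was higher by 4.71, Socs3, a feedback inhibitor of cytokine signalling, by 4.00, the adhesion molecule gene Icam1 by 3.87 and Nfkbiz by 3.70. Il1b and Il6, which encode inflammatory cytokines, were higher by at least 4.42 and at least 4.33, and the chemokine gene Ccl2 by at least 3.42. Of 16 measured members of the IL-18 pathway list, 7 were at least 2-fold higher and 0 lower (median 0.87, percentile 100). These 7 were Pycard, Nfkbia, Il1b, Il6, Ccl2, Icam1 and Vcam1. The list had 33 members on the array, and genes of the IL-18 receptor chains and binding protein were not among the 7. The list median therefore does not show that IL-18 signalling rose. Macrophage markers had 10 of 16 higher and 0 lower (median 1.25, percentile 100), with C1qb at 2.06, Mpeg1 at 1.91 and Fcgr3 at 1.83. C1qb, C1qc and Fcgr3, like Icam1 in the IL-18 pathway list, were at least 2-fold higher with banding in wild type too.

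Fn1, which encodes fibronectin, was higher by 3.78 in the banded IL-18 null array, Postn, which encodes periostin, by 3.37, Ccn2 by 3.01 and Col5a2 by 3.0. Fn1 and Postn were at least 2-fold higher with banding in wild type too. Timp1, an inhibitor of matrix metalloproteinases, was higher by at least 4.37. Mt2, a metallothionein, was higher by 3.69, and the glucocorticoid-response list that holds it had 7 of 13 members higher and 0 lower (median 1.11, percentile 100), with Sgk1 at 2.02 and Errfi1 at 1.94. Interferon-response genes had 6 of 19 higher and 0 lower (median 0.33, percentile 98.8), with Cxcl10 at least 2.09 higher and Ifit3 at 1.78. Antigen-presentation genes had 3 of 8 higher and 0 lower (median 0.69, percentile 99.8), with Ctss at 2.25. Immediate-early genes were mixed, with 5 of 18 higher and 4 lower. Gadd45b was higher by 2.87, Ier5 by 2.81 and Atf3 by 2.49, while Fos was at -1.45.

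In the banded IL-18 null array the fatty acid oxidation list had a median below 0 while nearly all its members stayed within 2-fold. The median was -0.30 (percentile 0.0), with 24 of 26 members within 2-fold, 0 higher and 2 lower: Mlycd, malonyl-CoA decarboxylase (-1.99), and Ppargc1a (-1.42). Citric acid cycle genes had a median of -0.17 (percentile 1.97, 0 higher and 1 lower of 17) and oxidative phosphorylation genes one of -0.06 (percentile 1.8, 0 higher and 0 lower of 62). Adult contractile and calcium-handling genes had 0 of 22 members past 2-fold either way (median -0.01, percentile 24.6). Single genes were ranked only if at or above the floor on both arrays, so bounds, such as that of Hspa1a, were left out. The lowest of these were Tns1 (-3.15), the inducible heat shock gene Hspa1b (-2.96) and Abcc9, a subunit of ATP-sensitive potassium channels (-2.73). Next were Pja2 (-2.69), the endothelial phosphatase gene Ptprb (-2.64) and Ppargc1b (-2.28). Dnajb1 (-1.92), Tmlhe (-1.88) and Wdr26 (-1.83) came after Mlycd. The Tns1 difference was 0.27 when probe sets that can cross-hybridise were left out.

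The count between the IL-18 null arrays was 459 of 4827 genes, 337 higher and 122 lower in banded; it was 262 and 153 after quantile normalization. Of the 20 genes with the largest differences among those at or above the floor on both arrays, 8 had other measured probe sets. These were at least 2-fold the same way in 4 and in the opposite way in 0.

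**Figure D3:**
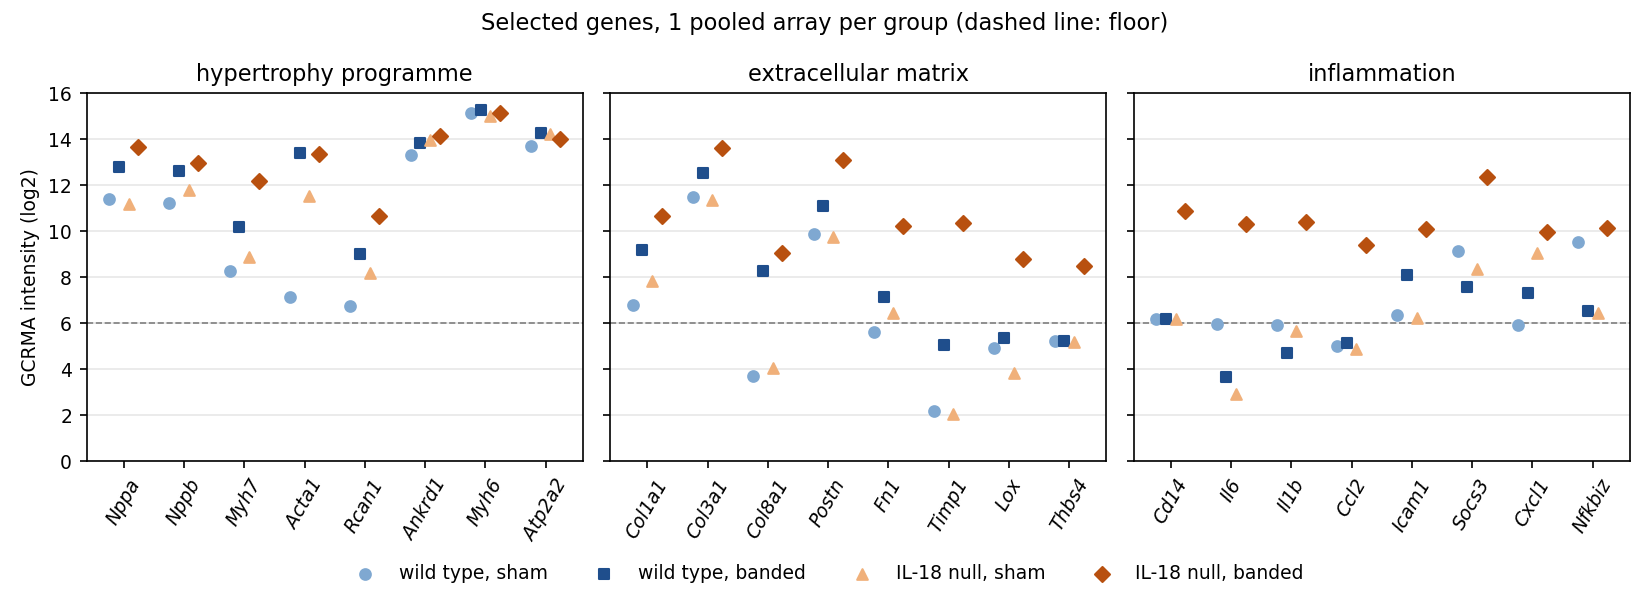
GCRMA log2 intensity of genes from the hypertrophy, extracellular matrix and inflammation groups, 1 point per pooled array, with the floor at log2 6 as a dashed line. Il6 is at 10.33 in IL-18 null banded and below the floor on the other 3 arrays, and Nppa is higher in both banded arrays (12.82 and 13.68) than in both sham arrays (11.41 and 11.18).

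Between the sham arrays, several genes of muscle energy use were among the largest differences, higher in IL-18 null than in wild type. This comparison shares the wild-type sham array with wild-type banding, so the results for these genes are not independent of those above. Bsg was higher by 6.47, Ckm by 6.35, Atp5g2 by 5.29, Pfkm by 5.27, Map1lc3a by 5.06, Ogdh by 5.03, Eif5a by 4.76, Hadha by 4.58 and Acta1 by 4.37. Glucose and glycogen genes had 11 of 22 members higher and 0 lower (median 0.97, percentile 100), and contractile genes 5 of 22 higher and 0 lower (median 0.50, percentile 99.7). The lists that hold Hadha and Ogdh did not stand apart here either: fatty acid oxidation genes had 8 of 26 higher and 0 lower (median 0.09, percentile 88.3) and citric acid cycle genes 5 of 17 higher and 0 lower (median 0.13, percentile 85.6). The heat shock and endoplasmic reticulum stress list had 7 of 21 higher and 0 lower (median 0.32, percentile 98.0), with Hspa1b at 4.67, Hspa1a at least 4.66 and Dnajb1 at 3.23. Lower in IL-18 null sham were Scd1 (-3.30), Nfkbiz (-3.09), Preb (-2.47), Cntd1 (-2.38), Cenpf (-2.32) and Sgk1 (-2.17), followed by Mbip, Nupl1, Rtp4 and Med21. Matrix genes had a median of 0.00 (11 of 45 higher and 2 lower), macrophage markers -0.06 (1 of 16 higher and 1 lower) and the IL-18 pathway list -0.01 (2 of 16 higher and 1 lower). Hypertrophy genes had a median of 0.22 (6 of 20 higher and 0 lower, percentile 94.6). The 3′ bias index was 4.74 in wild-type sham (3.04 as a bound with the floor) and 3.37 in IL-18 null sham. In all, 1094 of 4851 genes differed at least 2-fold, 789 higher and 305 lower in IL-18 null; the split was 668 and 637 after quantile normalization.

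Between the banded arrays, inflammatory, immediate-early and matrix genes were higher in IL-18 null than in wild type. Socs3 was higher by 4.80, Cd14 by 4.71, Nfkbiz by 3.63, the stress-induced transcription factor gene Atf3 by 3.43, Fn1 by 3.07, Errfi1 by 2.67, the chemokine gene Cxcl1 by 2.64, Phlda1 by 2.61, Mpeg1 by 2.53 and Mt2 by 2.51. The IL-18 pathway list had 7 of 16 members higher and 1 lower (median 0.90, percentile 100), macrophage markers 7 of 16 higher and 1 lower (median 0.92, percentile 100) and immediate-early genes 9 of 18 higher and 1 lower (median 1.01, percentile 100). Matrix genes had 14 of 45 higher and 3 lower (median 0.68, percentile 100), with Timp1 at least 4.37, Lox at least 2.81 and Thbs4 at least 2.48 higher. In the hypertrophy list 5 of 20 were higher and 2 lower (median 0.09, percentile 54.7). Myh7 was at 2.03, Rcan1 at 1.65 (-0.80 with the mean of its probe sets), Nppa at 0.86, Nppb at 0.33 and Acta1 at -0.05.

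Lower in IL-18 null banded than in wild-type banded were Tns1 (-5.19), the muscle methyltransferase gene Smyd1 (-4.66), Slc12a7 (-3.53), Psap (-3.14), Prkaca (-3.04), Abcc9 (-3.03), Pja2 (-2.94), the insulin-responsive glucose transporter gene Slc2a4 (-2.93), Apoe (-2.91) and Mrpl34 (-2.79). Fatty acid oxidation genes had 5 of 26 lower and 0 higher (median -0.15, percentile 0.18), glucose and glycogen genes 4 of 22 lower and 1 higher (median -0.26, percentile 0.05) and endothelial markers 5 of 19 lower and 0 higher (median -0.33, percentile 0.28). The 3′ bias index was 0.72 in wild-type banded and 3.01 in IL-18 null banded. In all, 665 of 4947 genes differed at least 2-fold, 282 higher and 383 lower; the split was 195 and 474 after cyclic loess.

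A total of 10 genes differed at least 2-fold the same way between genotypes in both surgeries, where independent lists would share 43.1 higher and 22.6 lower. The total was 4 with the mean of all probe sets, 6 and 16 with floors at log2 7 and 5, and 19 with no floor. Rcan1, named next, was at -0.80 between the banded arrays with the mean of its probe sets. Higher in IL-18 null were Cxcl1 (at least 3.06 in sham, 2.64 in banded), Hspa1b (4.67 and 2.24), Rcan1 (1.46 and 1.65), the sorting receptor gene Sorl1 (1.23, and at least 1.26) and Col1a1 (1.04 and 1.47). Lower were the Y-chromosome gene Uty (-1.37, and -2.37 as a bound), Zbtb16 (-1.33 and -1.59), Timp4 (-1.33 and -1.43), Snrpd3 (-1.54 and -1.32) and Gdap10 (-1.73, and -1.20 as a bound). Another 184 genes were higher in sham and lower in banded, against 58.6 for independent lists, and 54 lower then higher, against 16.7. Across genes the genotype differences in the 2 surgeries had Pearson's r of -0.469 and Spearman's rho of -0.549.

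The response to banding differed at least 2-fold between genotypes in 2137 of 5158 genes, with 1052 higher and 1085 lower in IL-18 null minus wild type. This split was 1471 and 912 after quantile normalization and 708 and 1284 after cyclic loess. Only genes at or above the floor on all 4 arrays were ranked, so bounds, such as that of Fos, were left out. Of the ranked genes, those with a higher response in IL-18 null were led by Nfkbiz (6.72), Socs3 (5.57), Atf3 (4.79), Cd14 (4.74), Cntd1 (4.33) and Scd1 (3.88). Those with a lower one were led by Bsg (-7.90), Ckm (-7.27), Atp5g2 (-7.22), Tns1 (-7.05), Map1lc3a (-7.00), Eif5a (-6.55) and Pfkm (-6.50). The IL-18 pathway list had 9 of 16 members with a higher and 3 with a lower response (median 1.27, percentile 100), and the macrophage list 8 of 16 higher and 2 lower (median 1.13, percentile 99.9). Glucose and glycogen genes had 1 of 22 higher and 14 lower (median -1.22, percentile 0). This contrast draws on all 4 arrays and so on all their differences in 3′ bias.

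**Figure D4:**
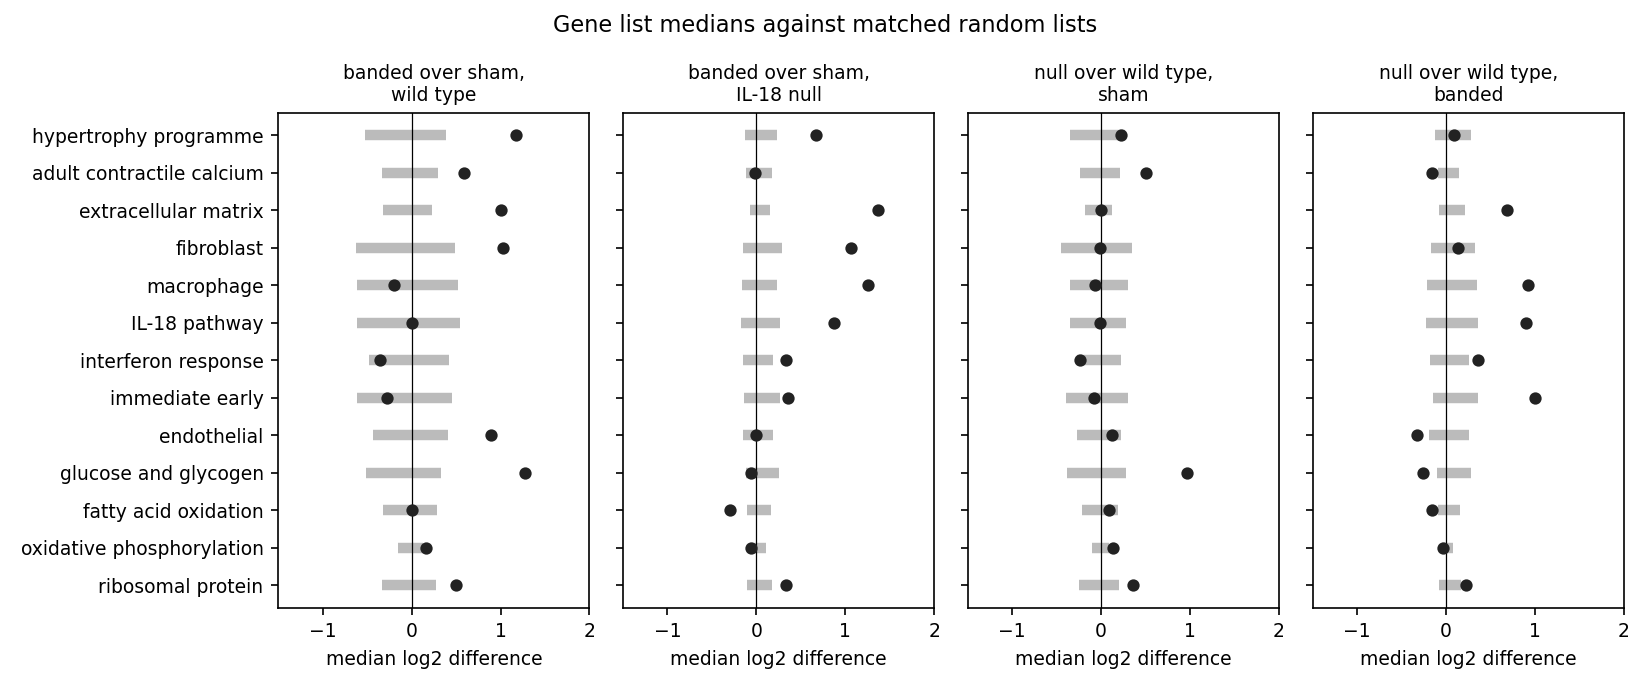
Median log2 difference (x axis) of 13 gene lists in the 4 comparisons of 2 arrays, as black points, with grey bars spanning 2 SD on each side of the median of 10000 matched random lists. Matrix and hypertrophy medians lie right of the bars in both banding comparisons, and the IL-18 pathway and macrophage medians in IL-18 null banded over sham and in banded IL-18 null over wild type.

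Scaling shifted the median of all genes. In wild-type banding it was -0.08 as deposited, -0.42 after quantile normalization and 0.10 after cyclic loess. Between the sham arrays it was -0.07 as deposited and -0.29 after quantile normalization. Between the banded arrays it was 0.11 and became -0.06 after cyclic loess. For the difference of responses it was 0.16, 0.42 and -0.07.

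An additive model of surgery and genotype over the 4 arrays, with 1 residual degree of freedom in limma, treats a response that differs between genotypes as error. With limma, 0 of 5158 genes passed an adjusted p of 0.05 for banding and 0 for genotype; 98 and 13 had an unadjusted p under 0.05, where 257.9 are expected by chance. The smallest unadjusted p in limma was 0.00137 for banding (Col8a1, adjusted p 1.00) and 0.00395 for genotype (Cxcl1). The fit took unfloored values, so its estimates for these genes (4.79 ± 0.72 SE and 2.89 ± 0.56 SE) draw on values below the floor: both sham arrays for Col8a1 and wild-type sham for Cxcl1. Adjusted over the list alone, limma gave 4 fibroblast genes for banding, Col1a1 (2.64), Mfap5 (2.57), Col3a1 (1.65) and Vim (1.34), each higher in banded in both genotypes (adjusted p 0.0488). It also gave Nppa in the atrial list (1.95, adjusted p 0.0214) and Acta1 in the skeletal muscle list (4.03, adjusted p 0.0451), and 0 genes in the other 28 lists. For genotype 0 genes passed over any of the 31 lists alone. No correction was made across the lists, and the atrial and skeletal muscle lists had only 4 and 3 measured members. Nppa and Acta1 are also in the hypertrophy list, and Col1a1, Mfap5 and Col3a1 in the matrix list. In those larger lists 0 genes passed for banding, so the calls depend on the list chosen. After quantile normalization, limma called 47 genes for banding, 46 higher and Fos lower, and 7 for genotype, with an infinite prior degree of freedom in place of 3.82.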

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

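The tests of the wild-type response as a whole cause, of exchanged labels and of the inflammatory genes, the choice of the control probe sets as a measure of bias, and the setting of the probe set disagreement against the spread of all genes were made only after the results were seen. By the mark set beforehand, a ratio of at least 1.5, that disagreement would have counted for 3′ bias, and the marks first set for Cd14 and for the nearness of IL-18 null sham would have counted against macrophages and a wild-type response; none is used so here. The genes below were picked because banded minus sham was at least 2-fold one way in one genotype and at least 2-fold the opposite way in the other. With 1 array per group the difference was not tested.

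Among all 5158 genes, 63 were higher with banding in wild type and lower in IL-18 null, and 44 went the other way. The 60 genes named for their size were partly ranked by the difference of responses, which favours opposite directions. Of these 60, 20 had opposite directions, a share that does not describe all genes. The response was higher in IL-18 null for Nfkbiz (6.72), Socs3 (5.57), Atf3 (4.79), Preb (4.50, a bound), Cntd1 (4.33), Errfi1 (3.75), Haus3 (3.62), Klf10 (3.53), Adamts1 (3.53), Rtp4 (3.30), Phlda1 (2.98) and Nupl1 (2.74). It was lower in IL-18 null for Atp5g2 (-7.22), Tns1 (-7.05), Ogdh (-6.24), Slc12a7 (-5.54, a bound), Psap (-5.53), Prkaca (-5.11, a bound), Mlycd (-4.75, a bound) and Abcc9 (-3.93). For Nfkbiz, Preb, Cntd1, Nupl1, Rtp4, Atp5g2 and Ogdh, unbanded IL-18 null sham also differed at least 2-fold from wild-type sham, the same way as wild-type banded. For these genes the signal of the wild-type sham array alone could give the wild-type direction. With the mean of all probe sets of a gene, 12 of these 20 kept opposite 2-fold directions, and Nfkbiz had 0.00 in both genotypes. Without probe sets that can cross-hybridise 15 kept them: Tns1 was at 1.75 in wild type and 0.27 in IL-18 null, Socs3 at 0.00 and 2.17, and Preb, Cntd1 and Nupl1 were not measured. A value of 0.00, as for Nfkbiz and Socs3 here, can arise where both arrays of a pair are set to the floor. It does not show that the gene was unchanged. After quantile normalization 18 of the genes kept opposite 2-fold directions. Control probe sets, which no comparison used, held a signal of their own: the 3′ minus middle value of Gapdh was 4.61 in wild-type sham and -0.16 in wild-type banded, and that of the dap control, whose middle probe set lay below the floor in wild-type sham, was 4.73 and 0.30.

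More genes differed 2-fold between the wild-type arrays (1743) than between the IL-18 null arrays (459). Against a difference in overall scale as the cause, the wild-type count was still 5.12 times the other after quantile normalization. That scaling itself moved the wild-type median of all genes from -0.08 to -0.42. After cyclic loess, with a wild-type median of 0.10, the counts were 1664 in wild type and 429 in IL-18 null. A stronger wild-type response as the whole cause cannot be told apart from an aberrant wild-type sham array: in 25.0% of the 1743 genes (435, exact 95% interval 22.9 to 27.1%) the unbanded IL-18 null sham array lay nearer to wild-type sham than to wild-type banded, but this rests on 1 array of another genotype. Unequal 3′ bias cannot be told apart from other sources of spread, because probe sets of one gene disagreed 2.30 times as much between the wild-type arrays (bootstrap 95% interval 2.19 to 2.42), while the SD over all genes was itself 2.13 times as large (2.35 times by a robust SD). Genotype labels exchanged between arrays cannot be told apart either, since the highest Il18 value (3.19) lay below the floor, and wild-type banded correlated best with IL-18 null sham (r 0.952); with exchanged labels, or arrays labelled by different protocols, every difference here could mean something else.

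Some inflammatory genes were higher in the banded IL-18 null array. The IL-18 pathway, macrophage, neutrophil, immediate-early and interferon lists together had 73 measured members. Of these, 29 were at least 2-fold higher than in IL-18 null sham, while 4 of the immediate-early genes were lower. Unequal 3′ bias cannot be told apart: of 29 members picked for exceeding the IL-18 null sham array 2-fold, 18 (62.1%, exact 95% interval 42.3 to 79.3%) also exceeded both wild-type arrays 2-fold, against 30.3% of all 337 genes picked so (25.4 to 35.5%), but the bias of the banded IL-18 null array was not shown to lie between theirs (3′ minus 5′ mean 4.84, against 4.81 and 1.33). IL-18 null sham had nearly the same means as IL-18 null banded (4.81 against 4.84, index 3.37 against 3.01), which speaks for similar bias in that pair, though single controls differed both ways (Gapdh 2.73 and 1.66, thr 4.55 and 5.78), so bias was not excluded. A larger share of macrophages stays open, and cannot be told apart by Cd14: it lay 3.50 above the median of 15 other macrophage markers (1.21 ± 0.65 SD, 9 of them at least 2-fold higher), but it was itself the top gene of the pattern. IL-18 deficiency under banding cannot be told apart from chance differences between pools, or from a different banding time, because there was 1 banded IL-18 null pool.

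Genes near Il18 differed between genotypes in both surgeries more often than others. Within 10 Mb, 3 of 66 genes differed 1.5-fold the same way (Sln, Sorl1 and Zbtb16), against 55 of 5085 elsewhere, an odds ratio of 4.36 (95% interval 0.849 to 14, Fisher's exact p 0.0376). DNA of the donor strain kept around the deleted gene may account for part of these, though the interval includes 1 and rests on 3 genes. With 2-fold as the threshold the odds ratio was 19.8 (2 of 66 genes, 95% interval 2.01 to 102, Fisher's exact p 0.00681). Both tests take genes as units and say nothing about whether other pools would repeat the differences. Zbtb16 is also in the glucocorticoid-response list and Sln in the atrial list, and an effect of lacking IL-18 on these genes was not tested.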

How the results depend on the processing

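The fit with the 3′ bias covariate was chosen after the control probe sets were seen. The cause of the changes below was not tested, apart from the thresholds and floors, which let more or fewer genes pass by construction. At 1.5-fold, 2840 genes differed with banding in wild type, 1182 in IL-18 null, 2195 between sham arrays, 1532 between banded arrays, 302 the same way with banding and 58 with genotype. With the mean of all probe sets the count for IL-18 null banding was 295, with 58 genes the same way with banding and 4 with genotype. A floor at log2 7 left 61 and 6 such genes, and a floor at 5 or no floor gave 16 and 19 for genotype. Quantile normalization gave 47 and 7 limma calls; all other alternatives gave 0. Single genes reversed as follows: Tns1 in IL-18 null to 0.27 without shared probe sets, and with the mean of probe sets Ppargc1a (0.40) and Fech (0.38) in wild-type banding and Rcan1 between banded arrays (-0.80). The oxidative phosphorylation median of wild-type banding was -0.0319 after quantile normalization. The covariate fit has as many terms as arrays: its banding term is fixed at 1.098 times the IL-18 null difference and -0.10 times the wild-type one, and its genotype term at 0.63 times the sham and 0.37 times the banded difference. It therefore restates those differences and tests nothing about the bias. These mixtures gave 598 genes for banding (1743 in wild type, 459 in IL-18 null) and 395 for genotype. Among the lists whose medians had the opposite sign to wild-type banding were contractile (-0.12), oxidative phosphorylation (-0.0977), glucose (-0.18), neutrophil (0.70), endothelial (-0.0742) and adipocyte genes (0.10), and among those opposite to the banded genotype difference were contractile (0.22), fatty acid (0.0119), glucose (0.47), interferon (-0.0165) and endothelial genes (0.0867). The immediate-early median of IL-18 null banding was -0.0052 with the mean of probe sets. Of the remaining alternative values, 1121 of single genes moved by less than the robust SD of all genes in that comparison and 111 by more; of list medians, 887 moved by less than the SD of the random medians and 294 by more, where a median near 0 could take either sign. Single animals could not be paired because each group holds 1 pooled array, while the additive fit compared banded with sham within genotype. Signal over background limited the reach: 7235 genes lay below the floor on all arrays.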

Other observations

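The comparison of the 3 splits of the arrays was chosen after the data were seen. Ribosomal protein genes were slightly higher in both banded arrays, with medians of 0.50 in wild type (8 of 26 at least 2-fold higher, 1 lower, percentile 99.4) and 0.33 in IL-18 null (0 past 2-fold, percentile 100), and of 0.36 and 0.23 in IL-18 null over wild type. Rplp0 (4.00) and Rps14 (3.75) led in wild-type banding. Insulin-like growth factor gene Igf1 was higher by 1.22 in IL-18 null banding and by 0.07 in wild type, and the tubulin gene Tubb6 by at least 2.40 and at least 0.28. Antioxidant and metal genes had 5 of 15 higher and 0 lower in wild-type banding (Gpx3 at least 5.76) and 4 higher and 1 lower in IL-18 null (Mt2 at 3.69, Hmox1 at least 1.67). The heat shock list had a median of -0.14 in IL-18 null banding (percentile 1.51), with Hspa1a at -4.66, a bound, and one of 0.12 in wild type that became -0.03 after quantile normalization.

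Markers of other cell types were thinly measured. Neutrophil genes had 4 measured members, with S100a8 at 1.18 and S100a9 at 0.95 in IL-18 null banding and at -1.67 and -3.41, both bounds, in wild type. Of T and NK cell genes 2 were measured (medians -0.63 and 0.02 with banding in wild type and IL-18 null), of B cell genes 1 (0.16 and 0.00), of red cell genes 1 (0.32 and 0.00) and of mast cell genes 0. Smooth muscle and pericyte markers had medians of 0.60 and -0.00, with Tagln higher by at least 2.32 and 1.26. Adipocyte genes had a median of -0.79 in wild-type banding (3 of 6 lower, led by Scd1 at -4.17) and 0.00 in IL-18 null. Atrial genes had medians of 1.19 and 0.43, with Myl4 at 2.59 and 0.22, and the 3 measured skeletal muscle genes 1.74 and 1.82. Cell cycle genes, 5 measured, had medians of -0.22 and 0.33, with Mki67 at least 1.84 higher in IL-18 null banding. Circadian genes had medians of 0.56 (-0.01 after quantile normalization) and -0.08, and Wnt signalling genes of 0.03 and 0.07.

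Sex chromosome genes had 2 measured members. Eif2s3y had log2 intensities of 9.33, 8.83, 9.04 and 9.38 in wild-type sham, wild-type banded, IL-18 null sham and IL-18 null banded, and Uty had 8.0, 8.37, 6.63 and 5.29. Strain marker genes had medians of -0.83 between the sham arrays (percentile 0.4) and -0.37 between the banded arrays (percentile 2.69), with Wdfy1 at -1.44 and -0.84, both bounds.

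When the 4 arrays were split in the 3 possible ways into pairs, banding gave 692 genes with a 2-fold difference of means, genotype 258, and the crossed split 746. The crossed split sets wild-type banded and IL-18 null sham against the others. Its value is the difference of banding responses between genotypes given above, with the sign reversed and at a fixed fraction of its size. The 2-fold mark was therefore stricter here, and the crossed split is not a separate measure of noise.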
